A study of Mus musculus with 20 samples.

How the data were processed

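Small RNA was sequenced from the livers of male C57Bl/6J mice kept on a high-fat diet, with 42% of energy as fat, over 12 weeks. Per the labels' protocols, each mouse was gavaged with corn oil (the control), with Aroclor1260 at 20 mg/kg, with PCB126 at 20 µg/kg or with both at these doses. Aroclor1260 is a commercial mixture of polychlorinated biphenyls (PCBs) and PCB126 is a coplanar, dioxin-like congener that binds the aryl hydrocarbon receptor (AHR). The labels give 5 livers per group, so the 20 libraries were taken as 20 animals in 4 groups of 5. Libraries were made from 1 µg of RNA with the QIAseq miRNA kit and sequenced in 2 runs of 75 cycles, per the labels.

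The authors deposited a table of raw counts with 2061 entries and 20 libraries, and each of the 20 columns was matched to its library by name. Trimmomatic 0.33 and the genome build mm10 are named in the submitters' processing notes. The aligner, the counting program, the miRNA annotation release, the use of the kit's molecular identifiers and the joining of the sequencing runs are not given in the sources used here. An entry is a mature miRNA of a given precursor, and 83 of the 1915 mature names have several precursors (229 entries). Among the 39 such names with at least 100 counts, 32 have entries whose smallest total is over 90% of the largest, so a read can be counted in more than 1 entry. These repeats hold 15.9% of all counts, and members of such families were read as uncertain. The strand setting of the counting is also not given. Every entry names a miRNA, and 432 entries have no count in any library.

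Library totals ran from 3275002 to 5540286 counts. A miRNA with 0 counts in a library could reach 0.541 to 0.916 CPM, the level of 3 counts, depending on the library's total. These limits use the raw totals, without the scaling described below. Such limits cover counting error only, since reads are not known to be independent molecules. The 40 pairs of libraries within groups differed by far more than sampling noise (lowest chi-square per degree of freedom 11.6), so no library was taken as a repeat of another.

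Counts were analysed in R 4.3.3 with edgeR 4.0.16. Entries were kept with filterByExpr by group (minimum count 10), which left 438 entries of 385 mature names. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values in the text are TMM-scaled. A quasi-likelihood model with a mean per group was fitted to all 20 libraries without covariates, with 16 residual degrees of freedom, and each contrast was tested two-sided. The common dispersion was 0.109, a biological coefficient of variation of 33%. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Standard errors (SE) and 95% intervals of log2 fold changes were taken from the fold change and the p of the same test. The contrasts were each exposure against control, the combination against each single exposure, PCB126 against Aroclor1260, the interaction (the departure from additivity on the log2 scale) and any difference among the 4 groups. Tests of the main effect of each compound, 10 livers against 10, were added after the data were seen.

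The miRNAs named are those with the smallest p. Up to 12 called in each direction were named in each comparison with control, filled to 10 with the next smallest p. In the other contrasts up to 5 called in each direction were named, or the 3 with the smallest p where none passed. From each list up to 2 members with the highest level and up to 2 with the smallest p were named, and so were the 10 miRNAs with the most counts. For a mature miRNA with several entries, the entry with the most counts is given. The 17 lists, the tests, the naming rule and most alternatives were fixed before the data were examined.

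The lists take every arm and copy of their members. They are hepatocyte-enriched miRNAs (miR-122, miR-192, miR-194, miR-148a, miR-802), the let-7 family, miR-17 and its paralogous clusters, the miR-200 family of epithelium and bile ducts (miR-200a, miR-200b, miR-200c, miR-141, miR-429), the miR-183 cluster, miRNAs of mesenchymal and stellate cells (miR-143, miR-145a, miR-145b, miR-199a, miR-199b, miR-214), the miR-29 family, immune cells (miR-142a, miR-223, miR-150, miR-155, miR-146a, miR-146b, miR-342, miR-511), red blood cells (miR-451a, miR-144, miR-486a, miR-486b) and endothelium (miR-126a, miR-126b). The others are miRNAs of other tissues (muscle, pancreas and neurons, such as miR-1a, miR-133a, miR-216a and miR-9), the Dlk1-Dio3 imprinted cluster, lipid and glucose metabolism, AHR-linked miRNAs (miR-132, miR-212, miR-191, miR-203), miRNAs linked to inducers of the receptors CAR and PXR (miR-802, miR-182, miR-200a, miR-200b, miR-429, miR-148a), DNA damage, hypoxia and stress, and the Sfmbt2 intron cluster (miR-297, miR-466, miR-467, miR-669). Some miRNAs stand in more than 1 list. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 17 lists in each contrast, and again with an estimated correlation and with fry. Camera compares a list with the other miRNAs, while fry asks whether its members move, on balance, one way.

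The share of counts taken by miR-122-5p and by the 10 most abundant miRNAs was compared by two-sided exact permutation tests of 5 against 5 livers. The correlation and covariance of fold changes between exposures were set beside 100 simulations of unchanged groups sharing the same controls, with each miRNA drawn separately, and beside 20 divisions of the controls. Counts of shared entries were set beside 100 such simulations after the data were seen.

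The alternatives were other scalings, other low-count filters, DESeq2 1.42.0, limma voom with quality weights, robust moderation, fits of only the groups compared, the replicate number as a block and the omission of each library in turn. Added after the data were seen were 1 entry per mature miRNA and fits without 2 libraries rich in muscle miRNAs. So were fits without the 4 libraries highest on the first principal component, and that component as a covariate. Each count of called miRNAs was also set beside 100 divisions of the libraries. Tables by run, by molecule or with other RNA classes were not analysed here.

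The scripts were tested on 20 sets of simulated counts for the combination against control, with 200 entries changed and about 449 tested. At these group sizes 33.5% of miRNAs changed 1.5-fold were called, 72.0% of those changed 2-fold and 94.7% of those changed 4-fold. At a log2 CPM of 5 or more the shares were 49.7%, 93.6% and 98.3%, and 37 of 785 calls (4.7%) were false. A list shifted 2-fold was recovered in 20 of 20 simulations, with 1 false call in 320 tests of unshifted lists. Each entry was drawn separately, so these false-call rates do not cover miRNAs that vary together or copies that hold the same reads.

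Precursor positions came from the RefSeq gene table for GRCm38.p6, the assembly behind mm10, and host genes from GENCODE M21. Of 107 entries named in the lists and comparisons, 5 had no match and are given without coordinates. Precursor sequences were compared with transcripts of other RNA classes with blastn 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.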

Results

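The liver miRNA pool on a high-fat diet was led by miR-122-5p, the main miRNA of hepatocytes (precursor on mm10 chromosome 18:65248861-65248926, in an exon of the lincRNA AC157910.3), with 27.4% of counts. After it came miR-192-5p (4.72%), miR-21a-5p (4.64%), let-7f-5p (4.09%), miR-126a-3p (3.38%), miR-101b-3p (2.65%), miR-16-5p (2.58%), miR-148a-3p (2.55%), miR-29a-3p (2.34%) and let-7a-5p (2.12%). These percentages set 1 entry of each miRNA against the counts of all entries, copies included, and so understate each miRNA's part. With 1 entry per mature miRNA in the total as well, miR-122-5p held 32.55% and miR-192-5p 5.62%. The shares by group that follow are over all entries. The share of miR-122-5p was 27.6 ± 2.63% in control, 26.7 ± 1.43% with Aroclor1260, 27.9 ± 1.10% with PCB126 and 27.3 ± 1.10% with the combination (SD, n = 5). The 10 most abundant miRNAs together held 56.3 ± 3.50%, 55.6 ± 1.97%, 57.5 ± 0.793% and 56.3 ± 1.23%. None of the 6 comparisons of these shares with control passed (exact permutation p from 0.444 to 1, smallest possible 0.00794, adjusted p of 1 in each).

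Striated-muscle miRNAs weighed most on the first principal component, which held 47.5% of the variance (10.1% and 6.7% for the next components). Control replicate 3 (16.71), Aroclor1260 replicate 3 (15.72), combination replicate 2 (9.82) and control replicate 2 (8.82) scored highest on it. Aroclor1260 replicate 1 (4.95) lay between these 4 and the other livers (at most -0.14). It was kept in the fits without the 4. After miR-1a-3p (loading 0.434) and miR-133a-3p (0.409) came miR-10b-5p (0.158), miR-205-5p (0.115), the neuronal miR-9-5p (0.096) and Dlk1-Dio3 members such as miR-381-3p (0.095) and miR-127-3p (0.094). The striated-muscle miRNA miR-1a-3p stood at 15970 CPM in control replicate 3 and 15400 CPM in Aroclor1260 replicate 3, against at most 453 CPM in the other 18 libraries. In the same livers miR-133a-3p reached 1831 and 2540 CPM and miR-206-3p 1076 and 331 CPM. The smooth-muscle miRNA miR-143-3p was at 26640 CPM in combination replicate 2, 19610 CPM in control replicate 2 and 16940 CPM in control replicate 3, with a median of 6721 CPM in the 16 livers other than the 4, and miR-145a-5p followed it (1286, 1015 and 956 CPM). The epithelial miRNA miR-205-5p was at 786 CPM in control replicate 3 and at most 65.0 CPM in any other liver. Cardiac and slow-muscle miR-499-5p, within Myh7b, was at 33.7 CPM in Aroclor1260 replicate 3 and at most 2.83 CPM elsewhere. The acinar miRNAs of pancreas, miR-216a-5p and miR-217-5p, were highest in PCB126 replicate 2 (28.6 and 11.4 CPM).

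**Figure D1:**
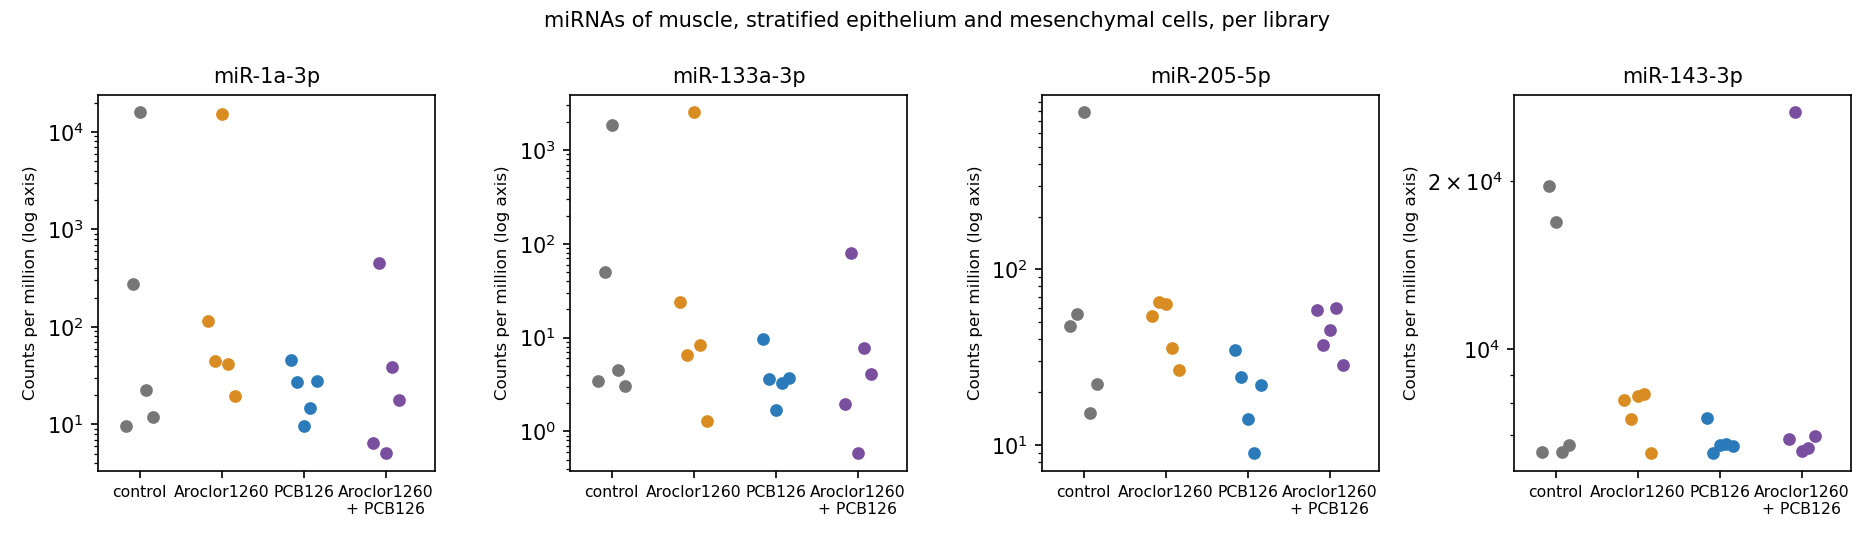
Level of miR-1a-3p, miR-133a-3p, miR-205-5p and miR-143-3p in each of 20 livers, in TMM-scaled CPM on a log axis, by exposure. miR-1a-3p is at 15970 CPM in control replicate 3 and 15400 CPM in Aroclor1260 replicate 3, and miR-143-3p at 26640 CPM in combination replicate 2.

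With Aroclor1260, miRNAs of immune cells rose as a list: 11 of 13 members were higher than in control, by a mean log2 fold change of 0.23 (camera adjusted p = 0.00626, and adjusted p = 0.71 with an estimated correlation). Among them miR-223-3p of myeloid cells was at 965 ± 242 CPM against 733 ± 115 CPM in control (SD, n = 5), a log2 fold change of 0.40 ± 0.15 SE. The leukocyte miRNA miR-342-3p, in an intron of Evl (chromosome 12:108658620-108658718), was at 312 ± 25.5 against 244 ± 36.2 CPM (0.35 ± 0.11), and miR-142a-3p of blood cells at 6473 ± 1597 against 5298 ± 1696 CPM (0.29 ± 0.20). miR-146a-3p (-0.58 ± 0.35) and miR-150-5p (-0.04 ± 0.31) were lower. No member passed over the list alone (0 of 13, smallest adjusted p 0.0628). Without control replicate 3 the list's adjusted p was 0.0632 and without Aroclor1260 replicate 2 it was 0.0647 (range over all alternatives 7.64e-05 to 0.71).

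The AHR-linked list was not called with Aroclor1260 (4 of 6 members higher, adjusted p = 0.157), but its member miR-132-3p, a CREB-responsive miRNA at chromosome 11:75173682-75173747 in an intron of 1700016P03Rik, passed over the list alone (1 of 6, adjusted p = 0.0195). It stood at 42.8 ± 8.83 CPM against 29.5 ± 5.83 CPM in control, a log2 fold change of 0.53 ± 0.16 (95% interval 0.20 to 0.86). Over all 438 entries its adjusted p was 0.474. The other arm, miR-132-5p, had 0.52 ± 0.21. The miRNA with the smallest p was miR-335-5p, in an intron of the imprinted gene Mest, at 482 ± 56.0 against 349 ± 46.8 CPM (log2 fold change 0.47 ± 0.12, adjusted p = 0.406), followed by its other arm miR-335-3p (0.68 ± 0.20, 0.474). The next smallest p of a lower miRNA was that of miR-7b-5p (-1.08 ± 0.35, adjusted p = 0.492). At an adjusted p of 0.569 were miR-1957a (0.46 ± 0.17), miR-676-5p (0.42 ± 0.16), the X-linked miR-450b-3p (0.45 ± 0.17) and the nearby miR-503-3p (0.33 ± 0.13). So was miR-499-5p (2.63 ± 0.95), high in Aroclor1260 replicate 3 alone. By edgeR 0 miRNAs were called and 37 entries had an unadjusted p under 0.05 (25 higher, 12 lower), where 21.9 are expected by chance. Copies that hold the same reads count separately and entries can vary together. No spread was set beside 21.9, so 37 is not read as an excess. DESeq2 called 0 with 27 under 0.05, and limma voom called 0 with 38.

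No other list was called with Aroclor1260, and outside the AHR-linked list no member passed over a list alone. With TMM scaling members were mostly lower in the let-7 family (17 of 24, adjusted p = 0.168) and the miR-29 family (6 of 8, 0.26; miR-29a-3p -0.11 ± 0.05), but mostly higher in both with library size alone. Members were also mostly lower in miR-17 and its paralogous clusters (12 of 18, 0.115; miR-19b-3p -0.17 ± 0.08), the miR-200 family (5 of 5, 0.115) and other tissues (6 of 8, 0.157). Mostly higher were red blood cells (5 of 5, 0.428), endothelium (4 of 4, 0.508) and DNA damage, hypoxia and stress (7 of 10, 0.204). In the last the p53 target miR-34a-5p was at 0.35 ± 0.18. The Sfmbt2 intron cluster was mostly higher too (28 of 31, 0.0718). It passed in some alternatives, as with RLE scaling (0.0197), and had 0.804 in another. Hepatocyte-enriched miRNAs were higher in 3 of 11 (0.567; miR-122-5p -0.11 ± 0.08, miR-802-3p 0.46 ± 0.19), CAR and PXR inducer-linked miRNAs in 3 of 8 (0.567), lipid and glucose metabolism in 10 of 22 (0.927; 15 with library size alone), Dlk1-Dio3 in 10 of 20 (0.265), mesenchymal and stellate cells in 7 of 13 (0.567) and the miR-183 cluster in 1 of 3 (0.508).

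**Figure D2:**
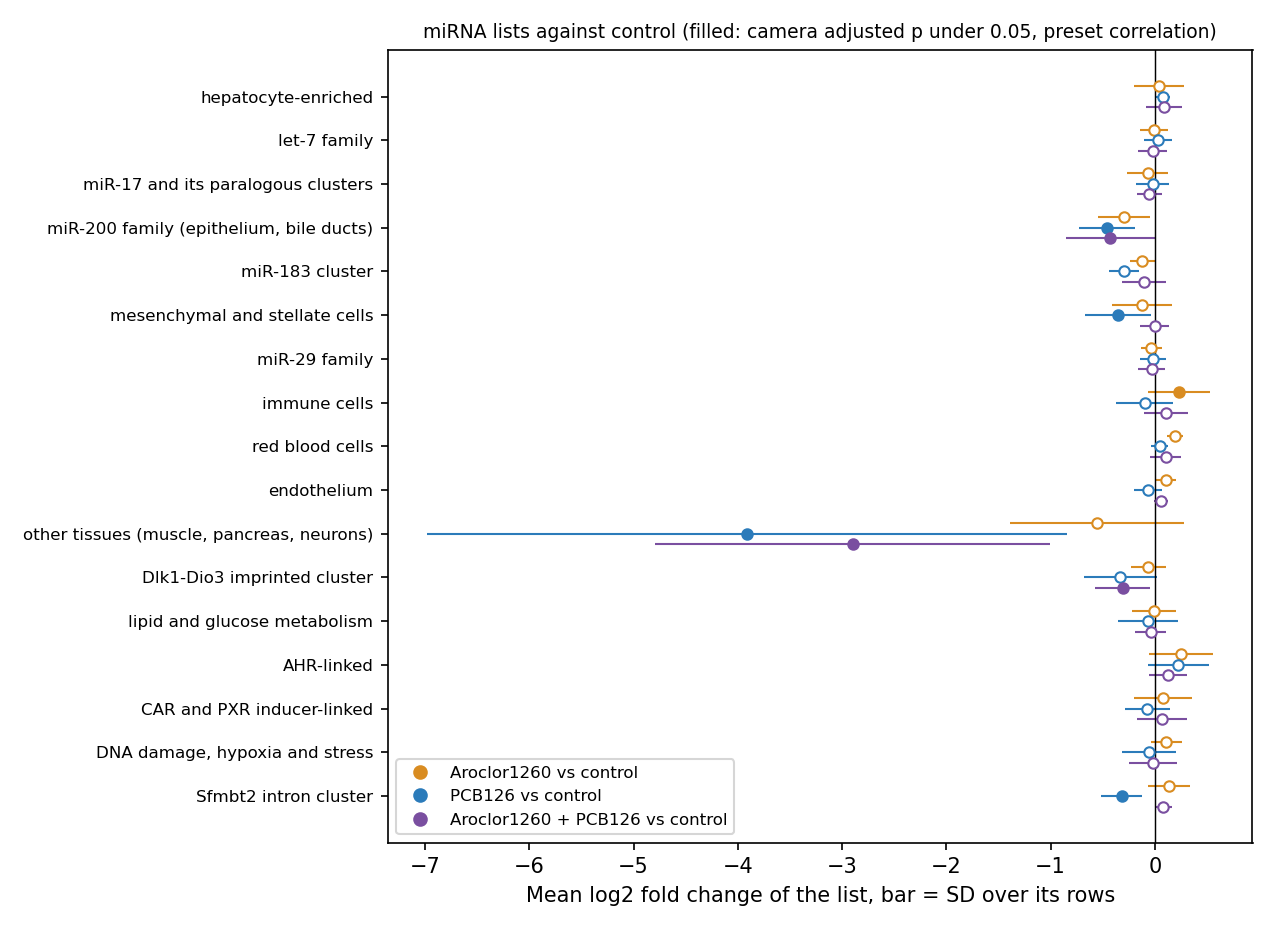
Mean log2 fold change of each of 17 miRNA lists in the 3 comparisons with control. Bars are the SD over the members of a list and filled points passed camera at the preset correlation; immune cells stand at 0.23 with Aroclor1260.

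With PCB126, epithelial, mesenchymal, other-tissue and Sfmbt2 intron cluster miRNAs fell as lists, and each of the 4 calls was lost in PCB126 vs control without control replicates 2 and 3, Aroclor1260 replicate 3 and combination replicate 2. All 5 members of the miR-200 family, which keeps epithelial cells from mesenchymal change by targeting Zeb1 and Zeb2, were lower (adjusted p = 0.00221, and adjusted p = 0.666 with an estimated correlation). miR-200c-3p stood at 12.8 ± 4.70 CPM against 23.1 ± 10.1 CPM in control (SD, n = 5), a log2 fold change of -0.85 ± 0.27 (-1.42 to -0.28) and it passed over the list alone (1 of 5, adjusted p = 0.0292). Beside it were miR-141-3p (-0.63 ± 0.35), miR-200a-3p (-0.26 ± 0.16) and miR-200b-3p (-0.25 ± 0.16). Its mean log2 CPM was 7.45 and 7.39 in control replicates 2 and 3, 6.37 to 6.92 in the other controls and 6.14 to 7.12 with PCB126, and without the 4 livers its adjusted p was 0.308 (range over all alternatives 9.09e-05 to 0.666). Of the mesenchymal and stellate cell miRNAs 12 of 13 were lower (0.00465, and adjusted p = 0.672 with an estimated correlation), among them the smooth-muscle miRNAs miR-143-3p (6843 ± 400 against 11269 ± 6465 CPM, -0.72 ± 0.38) and miR-145a-5p (-0.67 ± 0.32), with a mean log2 fold change of -0.35 and 0 past the threshold over the list alone. Control replicates 2 and 3 held most of the miR-143-3p of the controls, and without control replicate 2 the list's adjusted p was 0.489. Without the 4 livers the list turned to higher (0.85, range over all alternatives 0.000175 to 0.85).

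The miRNAs of other tissues were lower with PCB126 in 7 of 8 members (adjusted p = 0.0038, and adjusted p = 0.666 with an estimated correlation), and 7 passed over the list alone (smallest adjusted p 0.0244). These 7 are copies of miR-1a-3p, miR-133a-3p and miR-9-5p with near-equal counts, and the 8 members are 4 mature miRNAs. The striated-muscle miRNA miR-1a-3p was at 25.1 ± 14.1 CPM against 3259 ± 7109 CPM in control (log2 fold change -7.02 ± 2.47), and miR-133a-3p at -6.40 ± 2.30. The control level was that of replicate 3, without which the list's adjusted p in PCB126 vs control was 0.275, and without the 4 livers it was 0.914 (range over all alternatives 1.24e-05 to 0.914). In the Sfmbt2 intron cluster, a repeat-rich rodent cluster, 28 of 31 members were lower (1.39e-06, and adjusted p = 0.666 with an estimated correlation), as in miR-669a-3p (9.78 ± 1.29 against 11.4 ± 3.15 CPM, -0.23 ± 0.18) and miR-466b-3p (-0.51 ± 0.30). Its 31 members are copies of 11 mature names and many hold the same reads; 0 passed over the list alone (smallest adjusted p 0.255). Without the 4 livers the list's adjusted p was 0.143 (range over all alternatives 2.37e-10 to 0.666).

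No single miRNA passed over all 438 with PCB126. miR-6412 (21.9 ± 3.66 against 14.2 ± 1.40 CPM, log2 fold change 0.62 ± 0.16) and let-7c-1-3p (8.02 ± 1.41 against 5.27 ± 0.584 CPM, 0.60 ± 0.17) were higher and miR-205-5p was lower (20.9 CPM against 185 ± 336 CPM, -3.15 ± 0.85), each with an adjusted p of 0.217. Without control replicate 3 the value of miR-205-5p was -0.77. miR-5099 followed at 35.4 ± 3.12 against 27.3 ± 2.02 CPM (0.37 ± 0.11, interval 0.15 to 0.60, adjusted p = 0.231). At an adjusted p of 0.233 stood miR-6937-5p (1.00 ± 0.30), miR-6236 (0.90 ± 0.29), miR-6238 (0.88 ± 0.28), miR-1843a-5p (0.22 ± 0.07), miR-138-5p (-1.06 ± 0.33) and miR-200c-3p. By edgeR 0 were called and 30 had an unadjusted p under 0.05 (13 higher, 17 lower). DESeq2 called 0 with 25, and limma voom 0 with 28.

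The remaining lists were not called with PCB126, and besides let-7c-1-3p no member passed over a list alone. Upper-quartile scaling moves the median of all miRNAs by 0.12 (log2) against control here, and the directions given are those of TMM. Hepatocyte-enriched miRNAs were higher in 10 of 11 members (adjusted p = 0.175; miR-122-5p 0.01 ± 0.08) and AHR-linked miRNAs in 4 of 6 (0.175; miR-212-5p 0.68 ± 0.41, miR-191-3p 0.27 ± 0.14). In the let-7 family 14 of 24 were higher (0.504; mostly lower with RLE and TMMwsp scaling), with let-7c-1-3p past the threshold over the list alone (1 of 24, 0.0475). The miR-183 cluster was lower in 3 of 3 (0.175), Dlk1-Dio3 in 16 of 20 (0.445), immune cells in 8 of 13 (0.599; 5 of 13 with upper-quartile scaling; miR-142a-3p -0.12 ± 0.20) and CAR and PXR inducer-linked miRNAs in 5 of 8 (0.523). Higher members numbered 9 of 18 in miR-17 and its paralogous clusters (0.599), 4 of 8 in the miR-29 family (0.821), 4 of 5 in red blood cells (0.673), 2 of 4 in endothelium (0.599), 12 of 22 in lipid and glucose metabolism (0.874; fewer with RLE and TMMwsp) and 6 of 10 in DNA damage, hypoxia and stress (0.445).

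With the combination, miR-5099 and miR-335-5p rose. miR-5099 (chromosome 12:36816205-36816278, between genes) was at 42.3 ± 6.90 CPM against 27.3 ± 2.02 CPM in control (SD, n = 5), a log2 fold change of 0.63 ± 0.11 (0.41 to 0.86, adjusted p = 0.00553), or 1.55-fold. miR-335-5p (chromosome 6:30741299-30741396, in an intron of Mest) was at 515 ± 61.3 against 349 ± 46.8 CPM, a log2 fold change of 0.56 ± 0.12 (0.31 to 0.81, adjusted p = 0.0351). Without control replicate 3 the adjusted p of miR-5099 was 0.0658 and without combination replicate 3 it was 0.0594. That of miR-335-5p ranged from 0.00916 to 0.174 over the 20 omissions of 1 library and stayed under 0.05 only without control replicate 1, Aroclor1260 replicate 3, PCB126 replicates 1 or 2, or combination replicate 4. DESeq2 called 4, with miR-200c-3p and miR-6238 besides, and limma voom called miR-5099 and miR-335-5p. By edgeR 31 had an unadjusted p under 0.05 (18 higher, 13 lower).

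**Figure D3:**
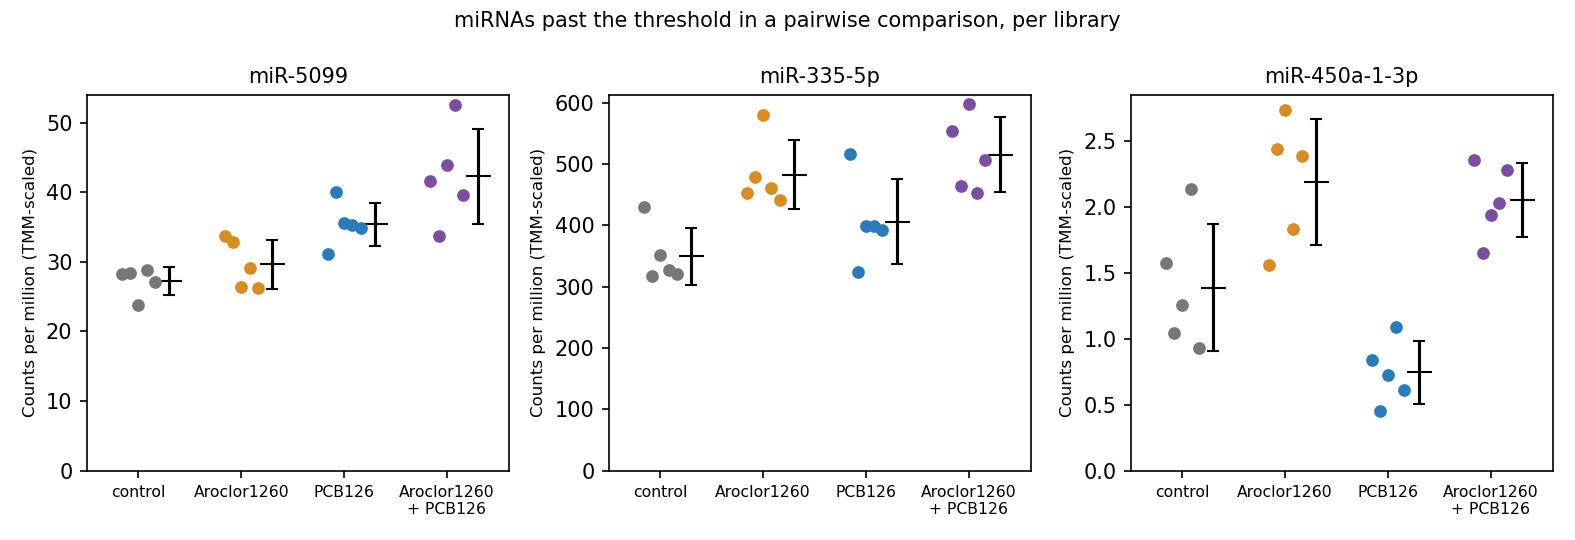
Level of miR-5099, miR-335-5p and miR-450a-1-3p in each liver, in TMM-scaled CPM, by exposure; bars are the mean and SD of 5 livers. miR-5099 goes from 27.3 CPM in control to 42.3 CPM with the combination.

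Short of the threshold with the combination were the epithelial miR-200c-3p (10.9 ± 1.92 against 23.1 ± 10.1 CPM, log2 fold change -1.10 ± 0.28, adjusted p = 0.119), miR-6238 (33.1 ± 5.59 against 15.8 ± 7.23 CPM, 1.05 ± 0.28, 0.156), miR-6236 (0.97 ± 0.29, 0.263), miR-335-3p (0.62 ± 0.20, 0.395), miR-6412 (0.49 ± 0.16, 0.395), let-7c-1-3p (0.49 ± 0.17, 0.42), miR-1957a (0.50 ± 0.17, 0.42) and miR-6240 (0.71 ± 0.26, 0.534).

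Epithelial, other-tissue and Dlk1-Dio3 miRNAs fell as lists with the combination, each with an adjusted p of 0.0351 and each with adjusted p = 0.805 with an estimated correlation. The miR-200 family was lower in 5 of 5 members, with miR-200c-3p past the threshold over the list alone (1 of 5, adjusted p = 0.00409) and miR-200a-3p at -0.14 ± 0.16. Other tissues were lower in 8 of 8 (miR-1a-3p -4.97 ± 2.24, miR-133a-3p -4.34 ± 2.06; 0 passed over the list alone). Control replicate 3 carried the control level: without it miR-1a-3p (0.34) and miR-133a-3p (0.24) turned to higher and the list's adjusted p was 0.449. The imprinted Dlk1-Dio3 cluster was lower in 19 of 20 members, as in miR-379-5p (-0.09 ± 0.49), miR-411-5p (-0.17 ± 0.52) and miR-381-3p (-0.92 ± 0.60), with 0 past the threshold over the list alone (smallest adjusted p 0.948). Its mean log2 CPM was high in control replicates 2 and 3 (3.31 and 2.77, other controls 1.39 to 2.24), combination replicate 2 (3.52) and Aroclor1260 replicate 1 (3.63). Each of the 3 calls was lost in Aroclor1260 + PCB126 vs control without the 4 livers, at 0.461, 0.226 and 0.189. Over all alternatives their adjusted p reached 0.805, from 0.00028 for the miR-200 family (call lost in 17 of 30), 6.1e-05 for other tissues (15) and 1.46e-06 for Dlk1-Dio3 (24). Over the omissions of 1 library it reached 0.254 for the miR-200 family (call lost in 10 of 20), 0.449 for other tissues (9 of 20) and 0.475 for Dlk1-Dio3 (16 of 20).

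The other lists were not called with the combination, and no member passed over a list alone. They were immune cells (10 of 13 higher, adjusted p = 0.148), Sfmbt2 intron cluster (29 of 31 higher, 0.14), hepatocyte-enriched (7 of 11 higher, 0.304; miR-122-5p -0.05 ± 0.08, miR-802-5p 0.40 ± 0.19), endothelium (3 of 4 higher, 0.308; miR-126a-5p 0.11 ± 0.06), let-7 family (12 of 24 higher, 0.366), miR-17 and its paralogous clusters (13 of 18 lower, 0.304), AHR-linked (4 of 6 higher, 0.447; miR-132-3p 0.21 ± 0.16), and CAR and PXR inducer-linked (4 of 8 higher, 0.447). The rest were lipid and glucose metabolism (14 of 22 lower, 10 with upper-quartile scaling, 0.513), mesenchymal and stellate cells (8 of 13 higher, 0.748), DNA damage, hypoxia and stress (5 of 10 higher, 0.748), miR-183 cluster (2 of 3 lower, 0.748), red blood cells (3 of 5 higher, 0.927) and the miR-29 family (4 of 8 higher, 0.946).

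PCB126 against Aroclor1260 differed in miR-450a-1-3p, of the X-linked miR-322, miR-503 and miR-542 cluster (chromosome X:53048154-53048244, between genes). It was lower with PCB126, at 0.743 ± 0.239 against 2.19 ± 0.479 CPM (SD, n = 5). The log2 fold change was -1.53 ± 0.29 (-2.14 to -0.92, adjusted p = 0.0208), on 147 counts in all 20 livers together. The PCB126 mean is at the level of 3 counts in those livers, 0.584 to 0.795 CPM by library total. The doses differ, 20 µg/kg of the congener and 20 mg/kg of the mixture, so this compares the exposures as given. miR-5099 was higher with PCB126 by 0.25 (interval 0.03 to 0.48, adjusted p = 0.311) and miR-335-5p lower by 0.25 (interval of the log2 fold change -0.50 to 0.00, adjusted p = 0.389). Without Aroclor1260 replicates 2, 3 or 5 the adjusted p of miR-450a-1-3p was 0.113, 0.145 and 0.123, and without PCB126 replicates 2, 3 or 5 it was 0.17, 0.0959 and 0.189. DESeq2 called 0 with 50 under an unadjusted p of 0.05, limma voom called 1 with 76, and edgeR had 50 (17 higher, 33 lower).

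Immune cell miRNAs were lower as a list with PCB126 than with Aroclor1260, with 11 of 13 point estimates lower (adjusted p = 0.00233, and adjusted p = 0.62 with an estimated correlation), and 4 passed over the list alone (smallest adjusted p 0.0294): miR-223-3p (-0.46 ± 0.15), miR-342-3p (-0.35 ± 0.11), miR-146b-5p (-0.54 ± 0.17) and miR-223-5p (-0.65 ± 0.24). The Sfmbt2 intron cluster was lower as a list, with 29 of 31 point estimates lower (1.23e-10, and adjusted p = 0.62 with an estimated correlation) and 0 members past the threshold over the list alone (smallest adjusted p 0.0513). Mesenchymal and stellate cells were lower in 13 of 13 (0.0829) and other tissues in 7 of 8 (0.343, with 4 past the threshold over the list alone, copies of miR-1a-3p and miR-133a-3p). In these the Aroclor1260 level is that of replicate 3, with miR-1a-3p at 15400 CPM against 19.5 to 114 CPM in the other 4 livers.

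The combination against PCB126 had no call by edgeR (0, with 23 under an unadjusted p of 0.05, 7 higher and 16 lower; DESeq2 0 with 24, limma voom 1 with 66). Next to the threshold was miR-450a-1-3p, higher by a log2 fold change of 1.45 ± 0.30 (0.83 to 2.08, adjusted p = 0.05004), then miR-320-3p (-0.49 ± 0.13, 0.149) and miR-671-5p, in a coding exon of Chpf2 (-0.47 ± 0.12, 0.149). Mesenchymal and stellate cell miRNAs were higher as a list (adjusted p = 0.00431, and adjusted p = 0.753 with an estimated correlation), with 13 of 13 point estimates higher, as in miR-143-3p (0.65 ± 0.38) and miR-199a-5p (0.26 ± 0.13), and 0 past the threshold over the list alone (smallest adjusted p 0.216). Without combination replicate 2, where miR-143-3p was at 26640 CPM, the adjusted p was 0.324 (range over all alternatives 0.000388 to 0.753). The Sfmbt2 intron cluster was higher as a list (4.73e-11, and adjusted p = 0.729 with an estimated correlation), with 29 of 31 point estimates higher, miR-669a-3p at 0.36 ± 0.18 and 0 past the threshold over the list alone (smallest adjusted p 0.0769).

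The combination against Aroclor1260 had no call by edgeR (0, with 12 under an unadjusted p of 0.05, 4 higher and 8 lower), while DESeq2 and limma voom each called 1, miR-5099 (with 10 and 14 under 0.05). miR-5099 was higher by 0.51 ± 0.11 (0.29 to 0.74, adjusted p = 0.0594), and miR-342-3p (-0.30 ± 0.11) and miR-671-5p (-0.31 ± 0.12) were lower at 0.999. No list was called (0 of 17, smallest adjusted p 0.162, hepatocyte-enriched).

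No miRNA was called for a departure from additivity of the exposures on the log2 scale, with a median 95% interval of 0.52 to each side. By edgeR 0 were called and 19 had an unadjusted p under 0.05 (9 higher, 10 lower), by DESeq2 0 with 13 and by limma voom 0 with 20. The smallest p were those of miR-671-5p (-0.63 ± 0.17, -0.99 to -0.27, adjusted p = 0.678), miR-7b-5p (1.53 ± 0.49, 0.866) and miR-205-5p (3.05 ± 1.13, 0.866), the last at 0.67 without control replicate 3. For miR-5099 the interaction was 0.14 (-0.18 to 0.46) and for miR-335-5p -0.12 (-0.48 to 0.23). As lists, mesenchymal and stellate cells were higher in the interaction (12 of 13 point estimates, adjusted p = 0.00437, and adjusted p = 0.725 with an estimated correlation; miR-143-3p 1.20 ± 0.54). So was the Sfmbt2 intron cluster (29 of 31, 0.00169, and adjusted p = 0.725 with an estimated correlation), and no member of either passed over the list alone. Without control replicate 2 or combination replicate 2, both high in miR-143-3p, the mesenchymal list had 0.215 and 0.139, and the Sfmbt2 list had 0.215, 0.0793 and, without Aroclor1260 replicate 5, 0.0779. Without the 4 livers apart on the first component the mesenchymal list turned to lower (range over all alternatives 8.27e-05 to 0.762) and the Sfmbt2 list had 0.91 (lost in 7 of 30 alternatives, 9.75e-08 to 0.91). With upper-quartile scaling the miR-200 family (0.0149), other tissues (0.0149), both higher, and AHR-linked miRNAs (lower, 0.0381) passed as well, and each had an adjusted p of 0.725 or more in another alternative.

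Over all 4 groups at once, miR-450a-1-3p and miR-5099 passed (2 called, smallest adjusted p 0.023, 31 with an unadjusted p under 0.05; DESeq2 2 and limma voom 2). In the tests of main effects added after the data were seen, with 10 livers against 10, miR-450a-1-3p (log2 fold change 1.05 ± 0.19, adjusted p = 0.00969) and miR-335-5p (0.41 ± 0.08, 0.23 to 0.58, 0.0274) rose with Aroclor1260, and miR-5099 (0.44 ± 0.08, 0.28 to 0.60, 0.00613) rose with PCB126. Among lists, immune cells (0.00161, and adjusted p = 0.574 with an estimated correlation) and the Sfmbt2 intron cluster (2.2e-08, and adjusted p = 0.707) rose with Aroclor1260. With PCB126 hepatocyte-enriched miRNAs rose as a list (11 of 11 point estimates higher, 0.0139). Their mean log2 CPM was 11.028 in control, 11.091 with Aroclor1260, 11.122 with PCB126 and 11.131 with both. The miR-200 family (0.0102), other tissues (0.0102, with the muscle miRNAs of control and Aroclor1260 replicates 3) and the Sfmbt2 intron cluster (0.000241) fell. Each of these PCB126 lists had adjusted p = 0.907 with an estimated correlation. Main-effect lists were not refitted with livers left out or with 1 entry per mature miRNA. For PCB126 against control, the 3 that fell lost their calls without the 4 livers.

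The exposures shared no called miRNA with each other (0 in each pair by edgeR, 0 expected). Aroclor1260 and PCB126 had 0 calls each against control, so no overlap was possible and this says nothing on likeness. At an unadjusted p under 0.05, PCB126 and the combination shared 8 higher and 8 lower entries, such as miR-5099, miR-6238 and miR-200c-3p. Each copy of a miRNA counts as an entry here. Aroclor1260 and the combination shared 9 higher and 2 lower, such as miR-335-5p, and Aroclor1260 and PCB126 shared 4 higher and 6 lower. Unchanged groups with the same controls shared a mean of 2.41 higher and 1.78 lower for the first pair (at most 7 and 7 in 100 simulations), 2.44 and 1.82 for the next (at most 8 and 6) and 2.74 and 2.00 for the last (at most 7 and 6). These simulations draw each entry separately, so copies that hold the same reads are not covered, nor are livers that differ in many miRNAs at once. Counts above the simulated highest are therefore not read as a shared response. Across 438 entries, fold changes of PCB126 and the combination correlated at 0.70. Unchanged groups sharing the same controls gave a mean of 0.50 (0.26 to 0.72 in the middle 95% of 100 simulations), and divided controls gave 0.06. Aroclor1260 and the combination correlated at 0.52 (simulated 0.51, 0.26 to 0.73, divided controls -0.14). Aroclor1260 and PCB126 correlated at 0.263, just under the simulated 0.268 to 0.732 (mean 0.52, divided controls -0.23).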

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

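The tests of striated muscle in the samples and of the Aroclor1260 exposure as sources of the muscle miRNAs were chosen after the result was seen. In 176 groups of 5 livers, 8 (4.5%) held a liver set apart from the other 4, where chance gives about 1 in 20 groups. The value given is the gap to the nearest other liver over the group's whole range.

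Muscle miRNAs not tested for exposure drew attention through miR-208b-3p, a miRNA of cardiac and slow muscle, which had 82 counts in Aroclor1260 replicate 3 and 0 to 1 in the controls. miR-1a-3p, at 15970 CPM in control replicate 3 and 15400 CPM in Aroclor1260 replicate 3, and miR-133a-3p set the pattern. The only striated-muscle miRNA not looked at before, miR-133b-3p, was highest in the same livers (1 of 1, a share of 1), too few entries to test striated muscle as the source. In it the lowest Aroclor1260 liver was at 0.000919 of the highest control. The pattern was seen with an unexposed control high, so this ratio was not an independent test. The values argue against the exposure as the source: unexposed control replicate 3 had 199.4 CPM, and the second-highest Aroclor1260 liver 0.4868 CPM. Striated muscle taken along with those livers, such as diaphragm, is an untested hypothesis from the same data, and muscle RNA mixed in later stays open.

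Hepatocyte-enriched miRNAs were high in control replicate 1 (mean log2 CPM 11.27 against 10.95 to 11 in the other controls, value 0.849). Members of miR-17 and its paralogous clusters were low in control replicate 4 (5.86 against 5.98 to 6.01, value 0.767). In combination replicate 2, where miR-143-3p was at 26640 CPM, the mesenchymal and stellate cell list was high (8.73 against 7.62 to 7.83, value 0.814). There the miR-200 family (6.91 against 6.46 to 6.55, value 0.819) and the DNA damage, hypoxia and stress list (6.85 against 6.34 to 6.45, value 0.775) were high as well. miR-676-5p was high in control replicate 2 (log2 CPM 3.51 against 2.98 to 3.05, value 0.859) and low in PCB126 replicate 3 (2.85 against 3.38 to 3.58, value 0.73). miR-6937-5p was low in control replicate 1 (1.00 against 1.88 to 2.17, value 0.756). No explanation of these was tested.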

How the results depend on the processing

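Chosen after the data were seen were the tests with 1 entry per mature miRNA, without 2 livers rich in muscle miRNAs (control 3 and Aroclor1260 3), without 4 livers (these, control 2 and combination 2) and with the first principal component as a covariate, as were the main effects and the upper-quartile and TMMwsp scaling of lists. Where a value changed, the cause was not tested, except that omissions leave fewer livers.

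miR-5099 and miR-335-5p, called for the combination against control, were both called with RLE, TMMwsp and upper-quartile scaling, TMM without miR-122-5p, the stricter filter, limma voom, 1 entry per mature miRNA and the component as covariate. The count was 1 (miR-5099) with library size alone and without the 4 livers, 4 with DESeq2, and 0 with no filter, with only the groups compared and without the 2 livers. Besides omissions of 1 liver, the adjusted p of miR-5099 ranged from 0.000661 to 0.158 (lost in 3 of 16 alternatives) and that of miR-335-5p from 0.000661 to 0.233 (lost in 5 of 16). Leaving out 1 liver gave 0 to 3 calls: 0 without control 3 or combination 3 and 3 without PCB126 1.

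miR-450a-1-3p, called for PCB126 against Aroclor1260, was called with RLE, TMMwsp, library size alone, TMM without miR-122-5p, limma voom, robust moderation, the replicate block and the component as covariate. The count was 0 with upper quartile, no filter, the stricter filter, DESeq2, only the groups compared, 1 entry per mature miRNA, without the 2 livers and without the 4. With the stricter filter, only the groups compared and 1 entry per mature miRNA it was under the filter and not tested, so it was lost in 5 of the 13 alternatives that tested it. Its adjusted p ranged from 0.00389 to 0.422, and single omissions gave 0 to 1 calls, 0 without Aroclor1260 2, 3 or 5 or PCB126 2, 3 or 5.

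For the combination against Aroclor1260, miR-5099 was called (1) with the stricter filter, DESeq2, limma voom and without the 4 livers, and single omissions gave 0 to 1 (1 without combination 2). For the combination against PCB126, miR-450a-1-3p was called (1) with RLE, TMMwsp, library size alone, limma voom, without the 2 livers and with the covariate, and miR-320-3p (1) with upper quartile; single omissions gave 0 to 2 (2 without control 5, 1 without control 1, control 4 or PCB126 4). Aroclor1260 and PCB126 against control and the interaction had 0 calls by edgeR in each alternative and omission run, beside 37, 30 and 19 miRNAs at an unadjusted p under 0.05 and 0 by DESeq2 and limma voom. For any difference among the groups the count of 2 became 0 with upper quartile, no filter, without the 2 livers, without the 4 and with the covariate, and 1 with the stricter filter and 1 entry per mature miRNA, where miR-450a-1-3p was not tested, with 0 to 3 over single omissions. The main effect of Aroclor1260 (2) gave 1 with upper quartile, the stricter filter and DESeq2, and 0 with no filter, 1 entry per mature miRNA, without the 2 and without the 4 livers; single omissions gave 0 to 2. That of PCB126 (1, miR-5099) gave 7 with no filter, 2 with DESeq2 and 0 without the 2 livers and with the covariate; single omissions gave 1 to 2 (2 without Aroclor1260 5).

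Whether replicate numbers pair the livers was not settled. Of 30 pairs of groups and numbers 12 correlated above 0.1 (from -0.542 to 0.781), and 9 of 20 livers were closest to their own number. No chance level was set beside these counts. Control and Aroclor1260 replicates 3 correlated at 0.781, and control and combination replicates 2 at 0.646. These livers are those highest on the first principal component. Control and combination replicates 3 had the lowest value, -0.542. Shared handling by number was not tested. With the number as a block, 0 miRNAs passed for Aroclor1260 (29 at an unadjusted p under 0.05) and 0 for PCB126 (25), and 2 for the combination.

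Lists past the threshold numbered 0 with an estimated correlation and 0 with fry in each comparison with control, in the combination against PCB126, in PCB126 against Aroclor1260 and in the interaction. For Aroclor1260 the count of 1 became 2 with RLE, library size alone, the replicate block and upper quartile. It became 3 with TMMwsp, 0 without the 2 livers and 3 without the 4. The Sfmbt2 intron cluster, higher, was gained with RLE (0.0197), TMMwsp (0.021), upper quartile (0.0225), the block (0.0423) and without the 4 livers (0.000233). For PCB126 the count of 4 became 0 without the 4 livers and 5 with upper quartile, which added Dlk1-Dio3 (0.0129). It was 3 with 1 entry per mature miRNA and 3 without the 2 livers, where other tissues lost the call. For the combination the count of 3 became 2 with RLE and 1 with the block. It became 0 with TMMwsp, with 1 entry per mature miRNA and without the 2 livers. Without the 4 it was 2, immune cells (0.0298) and the Sfmbt2 intron cluster (0.0138) in place of all 3. For the combination against Aroclor1260 the count of 0 became 3 without the 4 livers. These were Dlk1-Dio3 (lower, 9.89e-05), other tissues (lower, 0.0118) and hepatocyte-enriched miRNAs (higher, 0.04). Aroclor1260 replicate 1, high in Dlk1-Dio3, was kept in that fit. For the combination against PCB126 the count of 2 became 4 with upper quartile, with the let-7 family and immune cells (each 0.0242). It was 3 with 1 entry per mature miRNA (immune cells, 0.0207). Without the 4 livers it was also 3, where Dlk1-Dio3 (lower, 0.000823) and immune cells (0.00261) came in and mesenchymal cells lost the call. For PCB126 against Aroclor1260 the count of 2 became 5 with upper quartile, with the let-7 family (0.00711), mesenchymal cells (0.0414) and other tissues (0.0203). It was 3 with RLE and with TMMwsp (let-7 family) and 3 without the 4 livers (mesenchymal cells). In the interaction the count of 2 became 1 with 1 entry per mature miRNA, 1 without the 4 (Dlk1-Dio3 lower, 0.000147, in place of both) and 5 with upper quartile, with the miR-200 family (0.0149), other tissues (0.0149) and AHR-linked miRNAs (lower, 0.0381). Each list gained in these runs had an adjusted p of 0.725 to 0.998 in another alternative. Single omissions gave 0 to 5 for Aroclor1260 (0 without control 3 or Aroclor1260 2), 3 to 7 for PCB126 (7 without control 1), 0 to 4 for the combination (0 without control 3, Aroclor1260 1 or 3, PCB126 3 or 5, or combination 1), 0 to 3 for the combination against Aroclor1260, 2 to 4 against PCB126, 2 to 5 for PCB126 against Aroclor1260 and 0 to 6 for the interaction (0 without control 2 or combination 2).

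Mesenchymal and stellate cell miRNAs reversed direction without the 4 livers, in PCB126 against control (adjusted p = 0.85, range over all alternatives 0.000175 to 0.85) and in the interaction (adjusted p = 0.316, range 8.27e-05 to 0.762). Over the other scalings the called lists kept their direction, and for the combination against control the highest adjusted p was 0.0579 for the miR-200 family, 0.0579 for other tissues and 0.083 for Dlk1-Dio3. Upper-quartile scaling moved the median of all miRNAs by 0.12 for PCB126 against control and by 0.15 for PCB126 against Aroclor1260. The Sfmbt2 intron cluster, with copies that share reads, had an adjusted p of 0.0229 for PCB126 vs control with 1 entry per mature miRNA and 0.143 without the 4 livers (range 2.37e-10 to 0.666).

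miR-499-5p with Aroclor1260 reversed without Aroclor1260 3 (log2 fold change -0.307), without the 2 livers (-0.152) and without the 4 (-0.161), and ranged from -0.307 to 2.9 over single omissions. The differences in share from control, in points, ranged over single omissions from -0.9452 to 0.9635 for the 10 most abundant miRNAs with the combination, from -1.658 to 0.2511 with Aroclor1260 and from 0.1678 to 2.076 with PCB126. For miR-122-5p they ranged from -0.9523 to 0.4574, from -1.622 to -0.2122 and from -0.4177 to 0.9921. The signs turned without control 2 or 3 (miR-122-5p with PCB126), control 4 or 5 (miR-122-5p with the combination), control 2 or 3 or combination 1, 4 or 5 (10 most abundant with the combination) and control 4 or 5 or Aroclor1260 3 (10 most abundant with Aroclor1260). The correlation of fold changes of PCB126 and the combination was 0.059 with divided controls, 0.852 with the stricter filter, 0.439 without the 2 livers and 0.482 without the 4 (single omissions 0.444 to 0.834, lowest without control 3). That of Aroclor1260 and the combination was -0.141 with divided controls and 0.66 without the 2 livers (0.471 to 0.71), and that of Aroclor1260 and PCB126 -0.23 with divided controls and 0.538 without the 4 (0.113 to 0.597).

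Of the values of single named miRNAs under all alternatives, 7181 stayed on their side or within their error. The call was lost in 36, 21 passed the threshold anew, 247 moved by more than their error and 3 reversed. A change of sign counted as reversed only for called miRNAs and those with the smallest p of a whole comparison. For the other named miRNAs it falls under stayed or moved. Among these, miR-1a-3p with the combination ranged from -7.56 to 0.343 over single omissions. Of the values of called lists 321 stayed, 97 lost the call and 2 reversed. The median 95% interval reached 0.37 (log2) to each side of an estimate, 1.29-fold, without correction for the number of tests. It is not a detection limit: in the simulations 33.5% of 1.5-fold and 72.0% of 2-fold changes were called. Smaller changes of most miRNAs, and larger ones of some, are thus not excluded. Tables of other RNA classes, of reads against molecules and of each run alone were not run, since the count table holds no such columns. Fits of only the groups compared give no separate value for the interaction, the main effects or any difference.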

Other observations

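The tests for tissue in 4 livers, for miR-205-5p alone, for miR-200c-3p alone, for the other epithelial miRNAs without control replicate 3 and for pancreas were chosen after the results were seen, and the hypotheses on miR-335-5p, miR-5099 and immune cells were formed then. miR-335-5p, in an intron of the imprinted gene Mest, and miR-5099 go with different compounds in the point estimates. miR-335-5p had a log2 fold change of 0.47 with Aroclor1260, 0.22 with PCB126 and 0.56 with both, and miR-5099 had 0.12, 0.37 and 0.63. Both may come from the compounds acting side by side, as a hypothesis, since the interaction was 0.14 (-0.18 to 0.46) for miR-5099 and -0.12 (-0.48 to 0.23) for miR-335-5p. The direct comparison of PCB126 with Aroclor1260, at doses that differ, left both under the threshold (adjusted p = 0.311 and 0.389). The adjusted p of miR-335-5p with the combination ranged from 0.000661 to 0.233 over the alternatives.

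Immune cell miRNAs, with miR-223-3p of myeloid cells and miR-342-3p of leukocytes, could reflect more leukocytes in livers exposed to Aroclor1260, but cells were not counted here. The list lost its call for Aroclor1260 against control without control replicate 3 (adjusted p = 0.0632) and without Aroclor1260 replicate 2 (0.0647). It kept its call for PCB126 against Aroclor1260 in 20 of 20 omissions of 1 liver (6.76e-05 to 0.0198). With an estimated correlation the values were 0.71 and 0.62 (ranges over all alternatives 7.64e-05 to 0.71 and 6.76e-05 to 0.62).

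miR-5099, miR-6236, miR-6238, miR-6240 and miR-6412 were higher than in control with PCB126 (median log2 fold change 0.62) and with the combination (0.71), and also with Aroclor1260 alone (median 0.46, from 0.12 for miR-5099 to 0.62 for miR-6236 and miR-6238). Without the 4 livers apart on the first component the median was 0.64 for the combination, a ratio of 0.897, and 0.58 for PCB126, a ratio of 0.939, which argues against other tissue as the whole source. Reads of other RNA classes may add to some of them: 2 of the 5 precursors, those of miR-6236 and miR-6240, match another RNA over 20 bases at 95% identity, while the longest match of miR-5099 was 12 bases, of miR-6238 13 and of miR-6412 14. The searched set held no cytoplasmic tRNA and part of the ribosomal precursor, so this stays open. Their mean level correlated with the library total at 0.249 (-0.217 to 0.623), by ranks at 0.041, and at -0.089 without the 2 livers farthest in total; the interval is too wide to exclude depth. A response to either compound also stays open.

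miR-205-5p and miR-200c-3p, both epithelial, were lower with PCB126 and with the combination, and without control replicate 3 the mean of the 4 fold changes was 0.264 of its full value, from -1.78 to -0.47. The parts go separate ways: the ratio was 0.0807 for miR-205-5p (-3.15 to -0.77 with PCB126, -2.01 to 0.35 with the combination) and 0.75 for miR-200c-3p (-0.60 with PCB126 and -0.86 with the combination without that liver). Epithelial tissue in control replicate 3 may thus be the source for miR-205-5p, and the tables argue against that liver as the whole source for miR-200c-3p. Control replicate 2 had the next highest miR-200c-3p (25.94 CPM, after 39.34 CPM in control replicate 3) and stayed in that fit. Other tissue in the controls as a group is therefore not excluded for miR-200c-3p. The other epithelial miRNAs had a median log2 fold change of -0.207 (SD 0.195), against a bound of -0.888 that control replicate 3 inflates. Without that liver the median was -0.207 (SD 0.141) and the bound -0.234, so a fall of the whole epithelial population stays open.

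The X-linked cluster of miR-450a-1-3p, miR-450b-3p and miR-503-3p may be higher as a whole with Aroclor1260. In the test of its miR-322, miR-351 and miR-542 entries, 5 in all, the main effect of Aroclor1260 had log2 fold changes of 0.15 (miR-322-5p), 0.11 (miR-322-3p), 0.03 (miR-351-5p), 0.27 (miR-542-5p) and 0.14 (miR-542-3p), with a camera p of 0.0205 and a p of 0.154 with an estimated correlation. Left out of that test as of the miR-450 and miR-503 names in which the pattern was seen were miR-503-5p (0.24), miR-450a-5p (0.29 at both precursors), miR-450a-2-3p (0.28) and miR-450b-5p (0.16). The pancreas miRNAs miR-216a-5p and miR-217-5p were highest in the same 4 livers (4 of 4), PCB126 replicate 2, control replicate 5, Aroclor1260 replicate 2 and combination replicate 4. miR-375-3p of islets shared 3 of them. The pattern was seen in these same miRNAs and no other pancreas miRNA had counts enough to test it, so its source stays open.

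Calls were also counted in 100 splits of the livers, the real one included. For PCB126 against Aroclor1260 (1 call, miR-450a-1-3p) 4 of the 100 splits gave as many calls of any miRNA, the highest other 1. This share is under 0.05 for this comparison taken alone. As the smallest share of 10 such counts, not corrected for their number, it does not exclude chance. It rests on 147 counts and a call lost in 6 of 20 omissions. Chance could not be excluded for the combination against control (2 calls, miR-5099 and miR-335-5p; 17 splits, highest other 43), any difference among the groups (2 calls; 25 splits, highest other 29), the main effect of Aroclor1260 (2 calls; 11 splits, highest other 29) or that of PCB126 (1 call; 7 splits, highest other 45). For comparisons with 0 calls by edgeR all 100 splits give as many: Aroclor1260 against control (highest other 15; 37 miRNAs at an unadjusted p under 0.05; DESeq2 and limma voom 0), PCB126 against control (3; 30; 0 and 0), the combination against Aroclor1260 (13; 12; 1 and 1), the combination against PCB126 (3; 23; 0 and 1) and the interaction (4; 19; 0 and 0). Splits with 29 to 45 calls may reflect a structure of the samples beside exposure, such as the 4 livers highest on the first component. This was not tested, since no splits were counted without those livers.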
